A study of Homo sapiens with 12 samples.

How the data were processed

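RNA from a human embryonic stem cell line was hybridised to 12 arrays on 2 Illumina Human-6 v2 BeadChips of 6 arrays each, with 200 ng of RNA per sample per the labels. The labels name 4 groups of 3 arrays: undifferentiated cells (hESC), cells differentiated for 14 days and not sorted (Diff), and a pair of populations sorted from such cultures by surface markers. Both sorted populations were positive for podocalyxin and CD24. They were low (Low) or negative (Neg) for GCTM-2, an antigen of undifferentiated stem cells. Per the labels, RNA was isolated with the Qiagen RNeasy Micro kit, checked on a Bioanalyzer and amplified with the Illumina TotalPrep kit. Replicates of a group were cultures of one line at consecutive passages. A p-value of a probe or gene is therefore set against the spread between cultures of that line, not between lines.

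The authors deposited an unnormalized table and a normalized table. The unnormalized table gives, per the file headers, the mean bead intensity of each probe from BeadStudio version 2.3.41 with no normalization and no error model. It also holds the detection score deposited for each probe and array, a fraction between 0 and 1 that equals 1 minus the detection p. The normalized table holds the authors' processed intensity on a linear scale. The labels' processing notes name BeadStudio and RMA for it without order or settings. Its 12 columns share the same minimum and maximum and nearly the same quartiles, and each of the 11 that could be matched ranks probes as the unnormalized column of that array does.

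In the unnormalized table the 8 columns of the last array of chip 2 (the array labelled Neg 3) carry another sample's identifier, so they were not used. The remaining 66 columns of the matched arrays, such as bead counts and errors, were not used either. The plan fixed before the data were examined was to normalize the unnormalized table with limma's neqc on all 12 arrays. Because that table could be matched for 11 arrays only, the authors' normalized intensities, which cover 12, were used on the log2 scale and neqc became an alternative on 11 arrays. The groups, comparisons, gene lists, thresholds, the rule for named genes and the other alternatives were fixed at the same time.

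A probe was kept if its detection score was at least 0.99, a detection p of 0.01, on at least 3 of the 11 arrays with scores. This kept 15370 of 48687 probes. A list pairing probes with genes gave a single gene symbol for 23675 probes, several for 35 and none for 24977. Symbols of 23639 probes were brought up to date by gene number from a RefSeq gene table of assembly GRCh38.p14, which was used for names only. Where a gene had several kept probes, the probe with the highest mean over the 12 arrays stood for it, which left 11272 genes.

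Groups were compared with limma 3.58.1 in R 4.3.3 (with data.table at version 1.17.8), with 1 fit over the 4 groups and 6 comparisons, empirical Bayes moderation and two-sided tests. P-values were adjusted by the Benjamini-Hochberg method over the kept probes of each comparison, and a probe was called at an adjusted p under 0.05. Gene lists, 27 with 565 entries in all, were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, each adjusted over all lists and comparisons of a setting. The 26 lists with at least 3 detected members were tested. At the preset correlation the test sets the members of a list against the other genes. Its p-value does not measure how a list varies between cultures, and it was also computed where a group held 1 array. For each list, counts of called members are given over all probes tested and adjusted over the list alone.

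The fit over 12 arrays called no probe. After that was seen, the fit to the 6 arrays of chip 1, an alternative fixed beforehand, was chosen as the source of the values given first for each comparison, with values over 12 arrays beside them for the lists and the genes named first. Chip 1 holds 2 hESC, 2 Diff, 1 Low and 1 Neg array, which leaves 2 residual degrees of freedom. The lone Low and Neg arrays are assumed there to vary like the hESC and Diff pairs, and their values carry no SD. Chip 2 likewise holds 1 hESC and 1 Diff array, assumed to vary like its Low and Neg pairs, and the arrays labelled Neg 2 and Neg 3 that set much of that spread differed widely. Its hESC array, hESC 3, is one that differed from the chip 1 arrays of its label. The fit over 12 arrays has 8 residual degrees of freedom.

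Genes were named by rule: the 12 largest called changes each way per comparison (5 for Low and Neg against hESC) among genes whose arrays did not overlap between groups, up to 4 called members of each list or 2 where none was called, and a fixed set of sort, pluripotency and kidney genes. The rule was applied to the fit over 12 arrays and to the fit to chip 1, and genes were left out for length. Where no array of a group detected a gene, or an array of it read under its detection limit, the fold is given as a lower bound. For it, values under an array's detection limit were raised to that limit, the lowest normalized value scored as detected on that array. The array labelled Neg 3, without scores, took the highest limit of the other arrays, 5.86 on the log2 scale. A median of a list described as taken with values raised to the detection limit was computed in the same way. For arrays, the number of arrays limits the precision. The median difference over all kept probes lay between -0.07 and 0.03 on the log2 scale over the 12 arrays and was -0.10 for Neg against hESC on chip 1.

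Alternatives were a block for chip, a block for replicate number, each chip alone, no detection filter, neqc (offset 16), quantile normalization without background correction, each array left out in turn, only the arrays of the compared groups, an estimated correlation for lists and another probe of a gene. Added after the data were seen were leaving out the arrays labelled hESC 3 and Neg 2 together, limma with an intensity trend, and chip 1 with 1 of its hESC or Diff arrays dropped. The fits were tested on simulated data of 15370 probes with 50 changed probes per size. For Diff against hESC, the 12-array fit recovered 74% of changes of 2 and 100% of changes of 4 on the log2 scale, and the 6-array fit 66% and 98%. In the other comparisons the 6-array fit recovered 10% to 34% of changes of 2 and 88% to 94% of changes of 4, and the 12-array fit 64% to 80% and 94% to 98%. The simulated noise was independent between probes and arrays, and no simulated array was unlike its label. The real arrays labelled hESC 3 and Neg 2 were unlike theirs. Of the 6 arrays of chip 2, 1 correlated most with the chip 1 mean of its own label. These rates therefore do not carry over to the 12 real arrays. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6.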

Results

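Transcript levels were measured on 12 arrays of the human embryonic stem cell line HES4, with 3 arrays for each of 4 labelled populations. The arrays labelled hESC held undifferentiated cells, and those labelled Diff held cells differentiated for 14 days and left unsorted. The arrays labelled Low and Neg held cells sorted from differentiated cultures that carried podocalyxin and CD24 and were low or negative for GCTM-2. The series title places the work in the search for renal precursor cells. Per array, 13262 to 15025 of 48687 probes were detected on the 11 arrays with detection scores. The mean unnormalized intensity ranged from 607 on the array labelled Diff 1 to 937 on the array labelled hESC 3. Chip 1 carried the arrays labelled hESC 1, Diff 1, Low 1, Neg 1, hESC 2 and Diff 2, and chip 2 the other 6.

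Pluripotency and mesenchymal genes separated the chip 1 arrays by label but did not do so on chip 2. NANOG, a core pluripotency factor (probe ILMN_1659013), read 11.14 and 11.04 on the log2 scale on the arrays labelled hESC 1 and hESC 2, and 4.17 on the array labelled Neg 1, but 10.98 on the array labelled Neg 2. COL3A1, a fibrillar collagen of mesenchyme (probe ILMN_1773079), read 3.84 and 7.84 on the hESC arrays of chip 1 but 14.58 on the array labelled hESC 3, and 6.42 on the array labelled Neg 2 against 15.10 and 14.88 on the other Neg arrays. Across kept probes, the array labelled Neg 2 correlated most with the array labelled hESC 2 (0.984), and the array labelled hESC 3 with the array labelled Diff 2 (0.984). The array labelled Neg 2 had a mean correlation of 0.851 with the other arrays of its own label. The array labelled Diff 1 set the second principal component, which held 16.4% of the variance. No pair of arrays was identical.

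**Figure D1:**
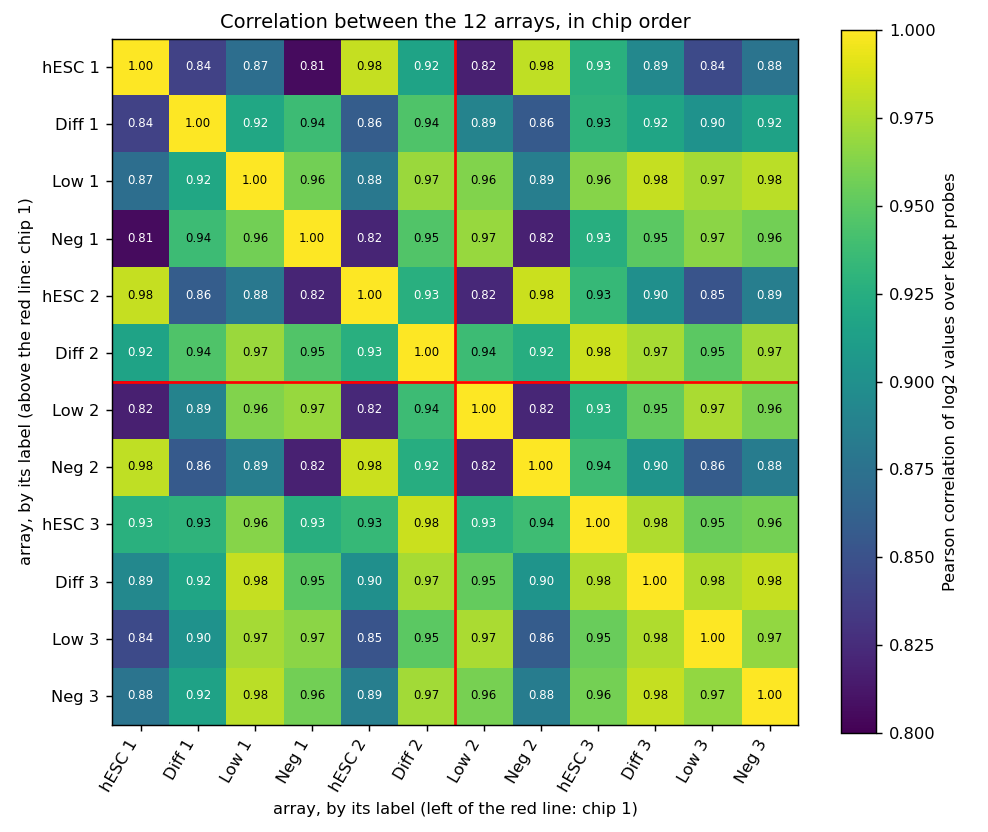
Pearson correlation of log2 intensities across the 15370 kept probes for each pair of the 12 arrays, in chip order, with the red lines parting the chips. The arrays labelled Neg 2 and hESC 2 correlate at 0.984, as do those labelled hESC 3 and Diff 2.

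Over all 12 arrays limma called 0 probes in each of the 6 comparisons, with 1583 probes at an unadjusted p under 0.05 for Diff against hESC, 4817 for Low against hESC, 1218 for Neg against hESC, 1340 for Low against Diff, 131 for Neg against Diff and 606 for Neg against Low. Chip 2 alone also gave 0 calls in every comparison, with 104, 500, 234, 301, 104 and 1130 probes unadjusted in the same order. Its spread rests on the Low pair and on the arrays labelled Neg 2 and Neg 3, which differed widely, so few calls were possible there. Chip 1 alone gave calls in the comparisons against hESC. With the arrays labelled hESC 3 and Neg 2 left out, limma called 1904 probes for Diff, 4571 for Low and 3925 for Neg against hESC. That fit still held the arrays labelled Low 2, Diff 3 and Neg 3. Low 2 correlated more with the chip 1 Neg array (0.9694) than with the chip 1 Low array (0.962). Diff 3 and Neg 3 correlated more with that Low array (0.9821 and 0.979) than with the chip 1 mean of their own label (0.9585 and 0.9575). The values given first below are those of chip 1, a choice made after the counts of called probes were seen. A test of whether the comparisons differed between the chips called 0 probes in each, with 681, 406, 2623, 379, 808 and 1442 unadjusted, and with the same wide spread of the Neg pair it could not show that the chips were alike. Across probes, the chip 1 and chip 2 differences correlated at 0.24 for Diff against hESC, 0.641 for Low against hESC, -0.321 for Neg against hESC, 0.18 for Low against Diff, -0.475 for Neg against Diff and -0.439 for Neg against Low. No call of a gene list held with an estimated correlation, with which every adjusted p over 12 arrays was 0.72 or more. With 2 residual degrees of freedom on each chip and adjustment over 156 results, few calls were possible there. Over 12 arrays its correlation was estimated with the unlike arrays labelled hESC 3 and Neg 2 in their groups. A call lost with it therefore does not show that a list was unchanged.

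**Figure D2:**
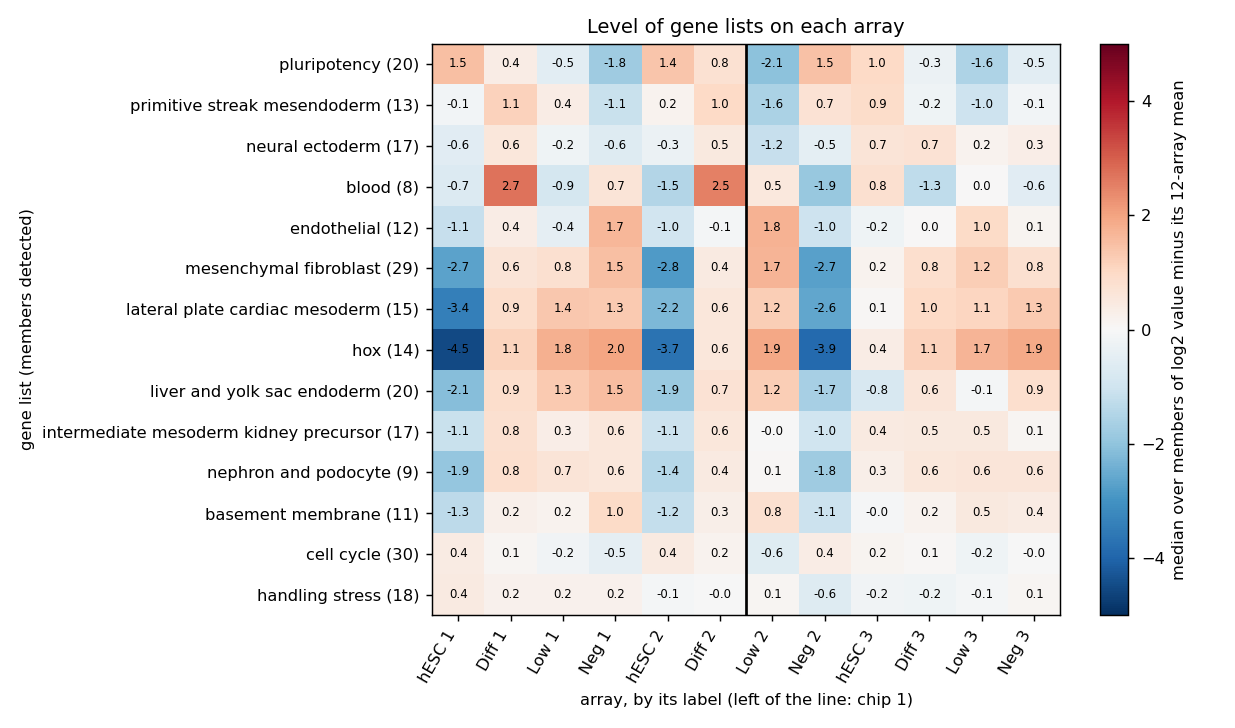
Level of each gene list (vertical axis, with its number of detected members) on each of the 12 arrays (horizontal axis), as the median over members of the log2 intensity minus its mean over the 12 arrays. The pluripotency list stands at 1.47 on the array labelled Neg 2 and at -1.77 on the array labelled Neg 1.

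The comparison of Diff with hESC asks what 14 days of differentiation changed in the whole culture. On chip 1, DCN, the matrix proteoglycan decorin (probe ILMN_1666672), read 13.84 ± 0.06 (SD, n = 2) on the Diff arrays against 3.96 ± 0.28 (SD, n = 2) on the hESC arrays, which did not detect it, and was at least 314-fold higher (adjusted p = 0.0084). COL3A1, which was under the detection limit on the array labelled hESC 1, rose at least 274-fold (adjusted p = 0.047) and COL6A3, another collagen, 144-fold (adjusted p = 0.027). The patterning gene HOXC6 was at least 70.1-fold higher, the water channel gene AQP1 at least 70.0-fold, and HBE1, the embryonic globin, at least 33.3-fold. The pluripotency factors POU5F1 and NANOG were lower by 1.27 and 1.21 on the log2 scale without passing the test (adjusted p = 0.12 and 0.078). Over 12 arrays, with values raised to the detection limit, the differences were 5.68 for DCN, 5.48 for COL3A1, 4.34 for HOXC6 and 2.30 for HBE1 on the log2 scale (adjusted p = 0.41 for each, from values as deposited).

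Of 29 mesenchymal and fibroblast genes, 17 rose and 0 fell on chip 1, and 21 rose adjusted over the list alone. The median was 3.32 on chip 1 and 2.36 over 12 arrays on the log2 scale (adjusted p = 0.26 on chip 1 with an estimated correlation). Of 15 lateral plate and cardiac mesoderm genes, 7 rose, or 14 adjusted over the list alone, with a median of 3.40 on chip 1, 3.16 with values raised to the detection limit and 2.52 over 12 arrays (adjusted p = 0.26 with an estimated correlation). They included FOXF1, a lateral plate transcription factor, at least 19.8-fold higher, and TBX3, at least 24.3-fold higher. Of 14 HOX genes, 11 rose, or 13 adjusted over the list alone. Their median was 4.93 on chip 1 and 3.65 over 12 arrays, or 3.68 and 2.84 with values raised to the detection limit (adjusted p = 0.26 with an estimated correlation). Of 20 liver and yolk sac endoderm genes, 14 rose, or 18 adjusted over the list alone (16 over the 12 arrays), with a median of 2.81 on chip 1, 2.13 with values raised to the detection limit and 2.25 over 12 arrays (adjusted p = 0.26 with an estimated correlation). AFP, the fetal serum protein alpha-fetoprotein, rose 21.0-fold and the serum protein gene AHSG at least 21.8-fold. Of 8 blood genes, 4 rose, all globins, or 6 adjusted over the list alone, with a median of 3.33, or 3.04 with values raised to the detection limit (adjusted p = 0.26 with an estimated correlation). Over 12 arrays the blood list was not called (median 1.70, adjusted p = 0.076), and on chip 2, with 1 array of each group, it was called the other way (median -2.02, adjusted p = 1.9e-05; adjusted p = 0.90 with an estimated correlation), with HBE1 at 8.41 on the array labelled hESC 3 and undetected on the array labelled Diff 3. On chip 1, HBZ was at least 13.3-fold and HBG2 at least 16.3-fold higher.

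Of 17 intermediate mesoderm and kidney precursor genes, 5 rose and 0 fell on chip 1, or 9 and 1 adjusted over the list alone. The median was 1.46 on chip 1 and 0.87 over 12 arrays, or 0.76 and 0.58 with values raised to the detection limit (adjusted p = 0.26 on chip 1 with an estimated correlation), and 0.05 on chip 2, uncalled. The genes that rose included the homeobox genes MEOX1, at least 13.3-fold, MEIS1, at least 17.3-fold, and MEIS2, 20.2-fold (adjusted p = 0.037). MEOX1 is also a marker of paraxial mesoderm, and both MEIS genes act in many embryonic tissues. OSR1, an early intermediate mesoderm gene (probe ILMN_1748383), was detected on neither the hESC nor the Diff arrays of chip 1. Of 9 nephron and podocyte genes, 4 rose, or 6 adjusted over the list alone: AQP1, TCF21, IRX3 and LRP2. TCF21, a transcription factor of podocytes and of other mesenchyme, was at least 9.16-fold higher, IRX3 6.39-fold and LRP2, the proximal tubule receptor megalin, at least 4.80-fold. The list's median was 2.47 on chip 1 and 1.84 over 12 arrays, or 1.17 and 0.77 with values raised to the detection limit (adjusted p = 0.26 with an estimated correlation). No kept probe measured PAX2, PAX8, SIX2 or WT1, whose probes were detected on 0 of 11 arrays.

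Some WNT target genes and some genes of other lists also rose in Diff on chip 1. Of 13 WNT target genes 9 rose on chip 1, or 11 with 1 fall adjusted over the list alone, among them LEF1, a transcription factor that answers WNT, at least 58.7-fold (median 2.46, 2.05 with values raised to the detection limit and 1.72 over 12 arrays; adjusted p = 0.26 with an estimated correlation), but on chip 2 the list's test turned down, uncalled (median 0.40, adjusted p = 0.82). Of 12 trophoblast and amnion genes 7 rose, or 10 adjusted over the list alone, with CDX2, which acts in trophectoderm and hindgut, at least 29.5-fold higher (median 2.77, 2.22 with values raised to the detection limit and 2.14 over 12 arrays; adjusted p = 0.26 with an estimated correlation). Of 11 basement membrane genes 6 rose, or 10 adjusted over the list alone, with NID2 at least 51.7-fold higher (median 1.46, and 1.14 over 12 arrays; adjusted p = 0.26 with an estimated correlation). Of 12 neural crest genes 6 rose, or 8 with 1 fall adjusted over the list alone, including SNAI2, a driver of epithelial to mesenchymal transition, at least 18.9-fold (median 1.90, and 1.19 over 12 arrays; adjusted p = 0.31 with an estimated correlation), but on chip 2 the list was called the other way (median -0.39; adjusted p = 0.90 with an estimated correlation). Of 12 endothelial genes 3 rose, or 4 adjusted over the list alone, TEK by 11.6-fold and PLVAP by at least 10.7-fold (median 1.04, or 0.80 with values raised to the detection limit; adjusted p = 0.33 with an estimated correlation). Of 17 neural ectoderm genes 6 rose, or 9 with 2 falls adjusted over the list alone, including PAX6, an eye and forebrain gene, at least 4.18-fold (median 1.12, or 0.66 with values raised to the detection limit; adjusted p = 0.26 with an estimated correlation). Over 12 arrays the endothelial and neural ectoderm lists were not called (medians 0.76 and 0.83).

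Of 20 pluripotency genes, 0 fell over all probes and 4 fell adjusted over the list alone on chip 1. The list's test called it lower (median -0.62, adjusted p = 2.3e-05; adjusted p = 0.26 with an estimated correlation), as it did over 12 arrays (median -0.87). Genes that fell included PLA2G4C, at least 3.99-fold lower, ANKRD35, at least 4.22-fold, and SNAR-A1, 5.97-fold. In all, 806 probes were called on chip 1, of which 675 were higher and 131 lower. Of these, 645 had the same sign on chip 2, where 58.6% of all kept probes did. Dropping 1 hESC or Diff array from chip 1 left 1 residual degree of freedom each time. No call remained with the array labelled hESC 1 or hESC 2 dropped, while calls remained with Diff 1 or Diff 2 dropped.

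The comparison of Low with hESC asks what set the weakly GCTM-2 positive sorted cells apart from undifferentiated cells. On chip 1 the array labelled Low 1 had less NANOG than the hESC arrays, 7.80 against 11.09 ± 0.07 (SD, n = 2), a 9.76-fold fall (adjusted p = 0.019). POU5F1 (probe ILMN_1679060) fell by 2.37 on the log2 scale (adjusted p = 0.048). UTF1, a chromatin factor of pluripotent cells, was at least 8.09-fold lower. DCN was at least 326-fold and AQP1 at least 127-fold higher. Over 12 arrays, with values raised to the detection limit, the differences had the same signs, -4.61 for NANOG, -3.77 for POU5F1 and 6.43 for DCN on the log2 scale (adjusted p = 0.11 for each, from values as deposited).

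Of 20 pluripotency genes, 12 fell and 0 rose on chip 1, or 17 fell adjusted over the list alone (19 over the 12 arrays). The median was -1.91 on chip 1 and -2.94 over 12 arrays (adjusted p = 0.26 on chip 1 with an estimated correlation). Of 15 lateral plate and cardiac mesoderm genes 10 rose, or 14 adjusted over the list alone, with a median of 4.31 on chip 1, 4.29 with values raised to the detection limit and 3.08 over 12 arrays (adjusted p = 0.26 with an estimated correlation). Of 14 HOX genes 11 rose, or 12 adjusted over the list alone, with a median of 6.02 on chip 1 and 4.49 over 12 arrays, or 4.54 and 3.70 with values raised to the detection limit (adjusted p = 0.26 with an estimated correlation). FOXF1 was at least 48.7-fold higher, and HOXB8 rose by 6.58 on the log2 scale. Of 29 mesenchymal genes 16 rose, or 25 with 1 fall adjusted over the list alone, with a median of 3.51 on chip 1, 3.32 with values raised to the detection limit and 2.87 over 12 arrays (adjusted p = 0.26 with an estimated correlation).

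Of 17 kidney precursor genes, 4 rose and 1 fell on chip 1, or 9 and 2 adjusted over the list alone. The median was 1.13 (adjusted p = 0.0051; adjusted p = 0.26 with an estimated correlation), and 0.61 with values raised to the detection limit. Over 12 arrays the list was not called (median 0.81, or 0.38 with values raised to the detection limit, adjusted p = 0.31). OSR1 was at least 1.41-fold higher on the array labelled Low 1 (adjusted p = 0.042) and read 6.04, 6.24 and 5.91 on the Low arrays against 4.19, 3.67 and 4.35 on the hESC arrays. Over 12 arrays it was at least 1.60-fold higher (adjusted p = 0.11). MEOX1 was at least 15.3-fold higher and MEIS2 rose 32.3-fold. Of 9 nephron and podocyte genes 4 rose on chip 1, as many adjusted over the list alone, with TCF21 at least 25.6-fold higher (median 2.43, or 0.90 with values raised to the detection limit; adjusted p = 0.29 with an estimated correlation), but the list was not called over 12 arrays (median 1.32, or 0.09 with values raised to the detection limit, adjusted p = 0.26). Chip 1 gave 1200 calls, 745 higher and 455 lower, of which 1128 had the same sign on chip 2, where 73.6% of all kept probes did. Leaving out the array labelled Neg 2 alone gave 3474 calls, and fitting only the 6 arrays of both groups 2585. Dropping either hESC array from chip 1 left 0 calls, and dropping either Diff array gave 2428.

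The comparison of Neg with hESC asks the same of the GCTM-2 negative cells. The array labelled Neg 1 had no detected NANOG, at least 46.6-fold below the hESC arrays of chip 1 (adjusted p = 0.0061), and POU5F1 fell 55.6-fold (adjusted p = 0.0072). DCN was at least 771-fold higher, MGP, a calcification inhibitor of matrix, at least 237-fold, and the growth factor gene IGF2, under the limit on the array labelled hESC 1, at least 383-fold. Genes of endothelial cells rose too: PLVAP at least 57.5-fold, CDH5, the endothelial cadherin, at least 22.3-fold, and the angiopoietin receptor gene TEK 34.8-fold. Over 12 arrays, with values raised to the detection limit, the differences were -2.53 for NANOG, 3.34 for DCN and 1.80 for CDH5 on the log2 scale (adjusted p = 0.51 for each, from values as deposited). On the array labelled Neg 2, PLVAP (probe ILMN_1786492) read 3.73 and CDH5 3.41.

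Of 20 pluripotency genes, 17 fell and 0 rose on chip 1, or 18 fell adjusted over the list alone. The median was -3.30 on chip 1, -3.02 with values raised to the detection limit, and -1.55 over 12 arrays (adjusted p = 0.26 on chip 1 with an estimated correlation). Of 12 endothelial genes, 6 rose, or 10 adjusted over the list alone, with a median of 2.86 on chip 1, 2.14 with values raised to the detection limit, and 1.11 over 12 arrays (adjusted p = 0.26 on chip 1 with an estimated correlation). Of 11 basement membrane genes 10 rose, as many adjusted over the list alone, with NID2, a nidogen, at least 100-fold higher (median 2.37, and 0.92 over 12 arrays; adjusted p = 0.26 with an estimated correlation). Of 30 cell cycle genes 5 fell, or 9 adjusted over the list alone, among them the replication licensing genes MCM5, 3.99-fold, and MCM6, 2.81-fold (median -0.84, and -0.33 over 12 arrays; adjusted p = 0.26 with an estimated correlation). Mesenchymal genes rose in 20 of 29 cases, or 22 adjusted over the list alone (median 4.26, and 1.57 over 12 arrays; adjusted p = 0.26 with an estimated correlation). HOX genes rose in 12 of 14, or 13 adjusted over the list alone (median 6.35, and 2.61 over 12 arrays, or 5.08 and 2.22 with values raised to the detection limit; adjusted p = 0.29 with an estimated correlation). On chip 2 both lists were called lower for Neg than for hESC, mesenchymal genes with a median of -1.09 (adjusted p = 0.00052) and HOX genes of -1.34 (adjusted p = 0.0073; adjusted p = 0.90 for both with an estimated correlation). There the basement membrane list turned to -0.28, the endothelial list to -0.48 and the cell cycle list to 0.02, none of them called, and the pluripotency list was -0.35, uncalled.

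Of 17 kidney precursor genes, 7 rose and 1 fell, or 8 and 2 adjusted over the list alone, but the list was not called on chip 1 (median 2.32, or 1.86 with values raised to the detection limit, adjusted p = 0.078) or over 12 arrays (median 0.65, or 0.33 with values raised to the detection limit, adjusted p = 0.60), and on chip 2 it was called lower (median -0.92; adjusted p = 0.90 with an estimated correlation). OSR1 was at least 3.83-fold higher on the array labelled Neg 1 (adjusted p = 0.011), which read 7.49, but it read 4.09 on the array labelled Neg 2. ITGA8, an integrin of kidney mesenchyme, was at least 5.72-fold higher. Of 9 nephron and podocyte genes 4 rose, or 5 adjusted over the list alone (median 2.24, or 1.10 with values raised to the detection limit; adjusted p = 0.31 with an estimated correlation), but the list was not called over 12 arrays (median 0.85, or 0.28 with values raised to the detection limit, adjusted p = 0.46) and was called lower on chip 2 (median -0.93; adjusted p = 0.90 with an estimated correlation). Chip 1 gave 2533 calls, 1463 higher and 1070 lower. Of these, 978 had the same sign on chip 2, where 44.0% of all kept probes did. Leaving out the array labelled Neg 2 alone gave 2620 calls. Dropping either hESC array from chip 1 left 0, and dropping either Diff array gave 4987.

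**Figure D3:**
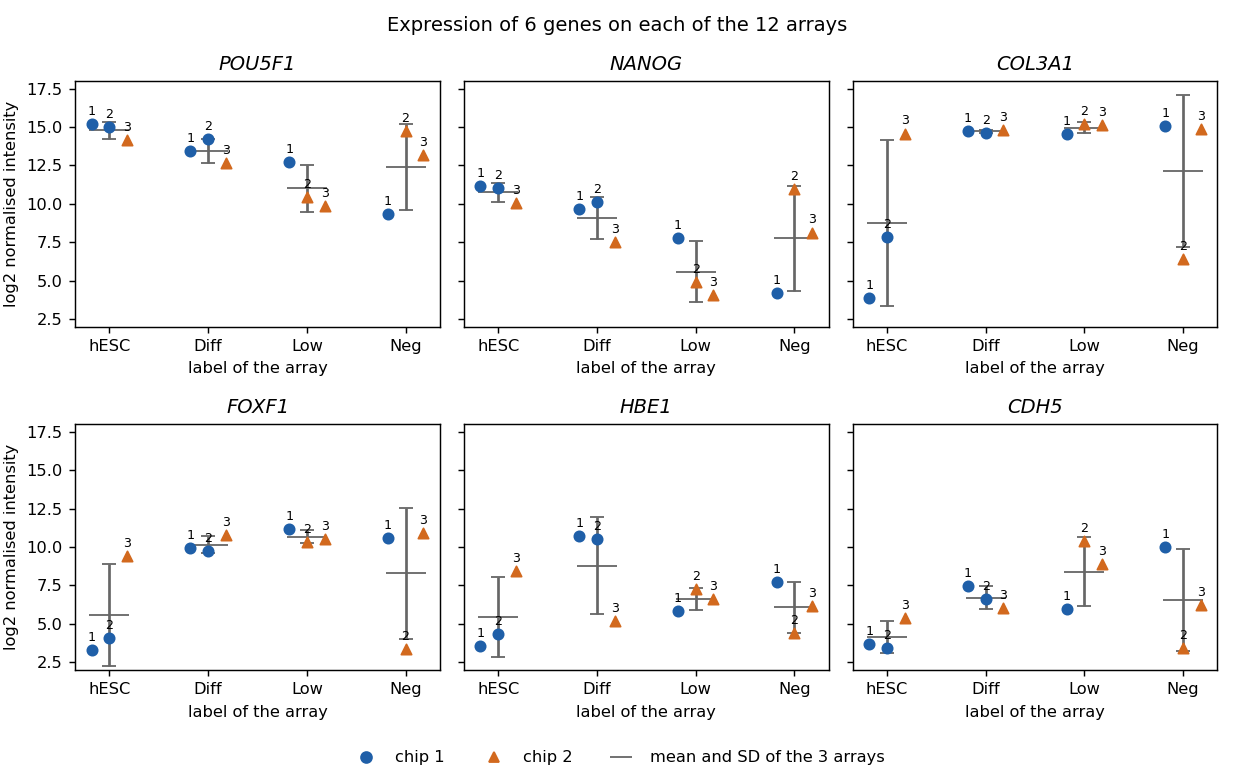
Log2 normalised intensity (vertical axis) of 6 genes on each array by its label (horizontal axis), with circles for chip 1, triangles for chip 2, replicate numbers beside the points, and the mean with SD of the 3 arrays. CDH5 reads 10.02 on the array labelled Neg 1 and 3.41 on the array labelled Neg 2.

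The comparison of Low with Diff asks how sorting for podocalyxin and CD24 with weak GCTM-2 changed the differentiated culture. NANOG was 7.80 on the array labelled Low 1 against 9.87 ± 0.31 (SD, n = 2) on the Diff arrays of chip 1, and over 12 arrays it was lower by at least 2.95 on the log2 scale (adjusted p = 0.35 and 0.56). Of 20 pluripotency genes, 0 passed over all probes and 9 fell adjusted over the list alone on chip 1. The list was called lower on chip 1 (median -1.10) and over 12 arrays (median -1.81, adjusted p = 2.1e-06; adjusted p = 0.26 on chip 1 with an estimated correlation). Globin genes were lower on the array labelled Low 1 than on the Diff arrays, HBZ at least 12.0-fold and HBG2 at least 14.8-fold (adjusted p = 0.29 and 0.35). The blood list's median was -3.33 on chip 1, or -2.98 with values raised to the detection limit, with 5 of 8 members lower and 1 higher adjusted over the list alone (adjusted p = 8.5e-06; adjusted p = 0.26 with an estimated correlation), and -2.08 over 12 arrays (adjusted p = 0.47), but on chip 2 it was called the other way (median 0.99, adjusted p = 0.0029; adjusted p = 0.90 with an estimated correlation). Endothelial genes had a median of -0.40 on chip 1, or -0.11 with values raised to the detection limit (adjusted p = 0.40), and of 1.04 over 12 arrays (adjusted p = 0.0062; adjusted p = 0.72 with an estimated correlation). On chip 1 limma called 0 probes, with 1379 unadjusted. Without the arrays labelled hESC 3 and Neg 2 it called 2, both lower, IGSF21 by 2.58 and AOX1 by 1.70 on the log2 scale (adjusted p = 0.026 and 0.032), named after their values were seen.

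The comparison of Neg with Diff asks the same of the GCTM-2 negative cells. On chip 1, NANOG was at least 20.1-fold and POU5F1 23.1-fold lower on the array labelled Neg 1 (adjusted p = 0.068 and 0.073), and EOMES, a mesendoderm factor, 14.9-fold lower (adjusted p = 0.068). Of 20 pluripotency genes 16 fell adjusted over the list alone and 0 over all probes. The median was -2.43 on chip 1, -2.05 with values raised to the detection limit, and -0.63 over 12 arrays (adjusted p = 0.00072; adjusted p = 0.26 on chip 1 with an estimated correlation). On chip 2 it was called the other way (median 0.69, adjusted p = 0.00093; adjusted p = 0.90 with an estimated correlation), and without the array labelled Neg 1 it was 0.13, uncalled. Of 13 primitive streak and mesendoderm genes 9 fell adjusted over the list alone and 0 over all probes, with medians of -2.13 on chip 1 and -1.22 over 12 arrays, or -1.69 and -0.56 with values raised to the detection limit (adjusted p = 0.26 on chip 1 with an estimated correlation). CDH5 was 7.83-fold and PLVAP 5.36-fold higher on the array labelled Neg 1 (adjusted p = 0.12 and 0.11). Of 12 endothelial genes 4 rose adjusted over the list alone on chip 1 and 0 over all probes (median 1.76, or 1.59 with values raised to the detection limit; adjusted p = 0.26 with an estimated correlation), but over 12 arrays the list's median was 0.11, or 0.49 with values raised to the detection limit (adjusted p = 0.27). The mesenchymal list was called in opposite directions, with a median of 1.05 on chip 1 and of -0.81 over 12 arrays (adjusted p = 0.26 and 0.75 with an estimated correlation). On chip 1 limma called 0 probes, with 1872 unadjusted.

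The comparison of Neg with Low asks how the sorted populations differed by GCTM-2 alone. On chip 1, with 1 array each, the array labelled Neg 1 had NANOG at least 4.77-fold and POU5F1 10.8-fold lower than the array labelled Low 1 (adjusted p = 0.39 for each). CDH5 was 16.8-fold higher (adjusted p = 0.39). Over 12 arrays the signs turned: with values raised to the detection limit, NANOG was higher by 2.08, POU5F1 higher by 1.39 and CDH5 lower by 1.11 on the log2 scale (adjusted p = 0.88 for each, from values as deposited). Of 20 pluripotency genes 9 fell and 1 rose adjusted over the list alone on chip 1, and 0 over all probes. The list was called lower on chip 1 (median -1.18, or -1.03 with values raised to the detection limit) and higher over 12 arrays (median 1.15, adjusted p = 0.00093; adjusted p = 0.26 and 0.72 with an estimated correlation). Endothelial genes were called higher on chip 1 (median 2.06, or 1.44 with values raised to the detection limit, with 3 of 12 members higher adjusted over the list alone and 0 over all probes) and lower over 12 arrays (median -0.56, adjusted p = 0.020; adjusted p = 0.26 and 0.73 with an estimated correlation). Without the arrays labelled hESC 3 and Neg 2 the medians were 0.22 and -0.01, neither called. These medians pool arrays that differed within a label, so they do not show that the populations were alike. NANOG read 7.80, 4.89 and 4.06 on the arrays labelled Low 1, Low 2 and Low 3, and 4.17 and 8.13 on those labelled Neg 1 and Neg 3. In the same order, CDH5 read 5.96, 10.36 and 8.89, and 10.02 and 6.23. On chip 1 limma called 0 probes, with 1069 unadjusted, and without those arrays 0, with 534 unadjusted.

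OSR1 was detected on all 3 Low arrays and on the array labelled Neg 1 but on no Diff array, which read 4.31, 4.57 and 4.87. It read 4.09 on the array labelled Neg 2, under its limit of 5.62. On the array labelled Neg 3, which has no detection scores, it read 5.20, under the limit of 5.86 taken for that array. It was at least 1.30-fold higher on the array labelled Low 1 and at least 3.53-fold on the array labelled Neg 1 than on the Diff arrays of chip 1, without passing the test (adjusted p = 0.41 and 0.085). The kidney precursor list's median for Low against Diff was -0.15 on chip 1 and -0.16 over 12 arrays, uncalled in both (adjusted p = 0.80 and 0.44). For Neg against Diff it was -0.18 on chip 1, uncalled. Over 12 arrays the list was called lower, with a median of -0.60, or -0.41 with values raised to the detection limit (adjusted p = 0.0013, or 0.72 with an estimated correlation). Without the arrays labelled hESC 3 and Neg 2 the median for Neg against Diff was no longer called. For Neg against Low it was 0.25 on chip 1 and -0.47 over 12 arrays, uncalled in both (adjusted p = 0.88 and 0.24), and with values raised to the detection limit the 12-array median turned to 0.05. RET, the receptor of the ureteric bud, read 8.72 and 8.73 on the hESC arrays of chip 1 and 8.89 and 8.67 on its Diff arrays. It was at least 9.41-fold lower on the array labelled Neg 1 than on those Diff arrays, without passing the test. LHX1, a gene of early nephrons, was at least 1.70-fold lower there (adjusted p = 0.13). SALL1 and EYA1 differed from hESC by -0.24 and 1.08 on the log2 scale in Diff on chip 1 (adjusted p = 0.68 and 0.066). Among the sort marker genes, PODXL, which encodes podocalyxin, differed from hESC by -0.12 in Diff, -0.06 in Low and 0.03 in Neg on chip 1 (adjusted p = 0.74, 0.92 and 0.94), and CD24 was lower by 1.47, 1.15 and 2.41 on the log2 scale without passing the test (adjusted p = 0.14, 0.29 and 0.055).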

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

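Results are differences on the log2 scale for lists (median over members) and counts of called probes, each against the fit over 12 arrays, and for every value below that moved or reversed the cause was not tested unless stated. On 12 arrays, 0 probes were called in any comparison with a chip block, a replicate block, no detection filter or an intensity trend in limma, nor on 11 arrays with neqc or quantile normalization, nor on the 6 arrays of chip 2. The replicate block changed the call of 4 of 156 list results. The deviations of arrays with the same number correlated between -0.576 and 0.563 across probes, which are not independent replicates, so pairing by number was not shown. Averaged over the arrays of each number in the other groups, the correlation was highest for the own number in 7 of 12 arrays. Signal over background limits genes near the detection limit, whose folds are lower bounds.

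Leaving out the arrays labelled hESC 3 and Neg 2, chosen after seeing the data, gave 1904 probes for Diff against hESC, 4571 for Low, 3925 for Neg, and 2 for Low against Diff. Chip 1 alone gave 806, 1200 and 2533 against hESC, and fitting only both compared groups gave 2585 for Low against hESC. Also chosen after seeing the data, chip 1 with the array labelled Diff 1 dropped gave 371, 2428 and 4987, with Diff 2 dropped 3748, 2428 and 4987, and with either hESC array dropped 0, where 1 residual degree of freedom is left. With an hESC array dropped, the spread came from the arrays labelled Diff 1 and Diff 2 alone, which correlated at 0.945. With a Diff array dropped, it came from those labelled hESC 1 and hESC 2 alone, which correlated at 0.983. Each of these 4 settings leaves 1 residual degree of freedom, so that number alone does not account for the counts of 0. In each of them 20 of 156 list results reversed, against 18 on all of chip 1, and 0 or 1 of 584 gene results. With each array left out in turn, the counts ranged from 0 to 3474 for Low against hESC, from 0 to 2620 for Neg against hESC, and stayed at 0 elsewhere.

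For the kidney precursor list, the estimated correlation ended the calls of Diff against hESC (0.87) and of Neg against Diff (-0.6), and the latter also ended with hESC 3 and Neg 2 out (-0.04) and on chip 1 (-0.18). Diff against hESC was 0.05 on chip 2, Low against hESC was 1.2 without both arrays and 1.13 on chip 1, now called, and Neg against hESC was 1.75 without both, now called, and -0.92 on chip 2. With each array left out in turn it ranged from 0.63 to 1.49 for Diff against hESC, 0.27 to 1.2 for Low against hESC, 0.05 to 1.45 for Neg against hESC, -0.26 to -0.01 for Low against Diff, -1.04 to -0.04 for Neg against Diff and -0.66 to 0.13 for Neg against Low.

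For the pluripotency list, the estimated correlation ended each call: Diff (-0.87), Low (-2.94) and Neg (-1.55) against hESC, Low (-1.81) and Neg (-0.63) against Diff, and Neg against Low (1.15). Neg against Diff was 0.69 on chip 2 and -0.24 with quantile normalization, Neg against Low was 0.22 without both arrays and -1.18 on chip 1, and Neg against hESC was -0.35 on chip 2. With each array left out in turn it ranged from -1.19 to -0.55, -3.44 to -2.56 and -2.52 to -0.85 for Diff, Low and Neg against hESC, -2.17 to -1.44 and -1.55 to 0.13 for Low and Neg against Diff, and 0.22 to 2.05 for Neg against Low.

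The following list results reversed. Without the arrays labelled hESC 3 and Neg 2, Neg against Diff: basement membrane 0.3, BMP and TGFB targets 0.2, HOX 0.94, lateral plate 0.53, liver and yolk sac 0.53, mesenchymal 0.53, nephron and podocyte -0.21, trophoblast and amnion 0.37, WNT targets 0.25. In the same setting, Neg against Low: basement membrane 0.16, HOX 0.05, liver and yolk sac 0.38. On chip 1, Neg against Diff: basement membrane 0.63, HOX 1.18, lateral plate 0.71, liver and yolk sac 0.81, mesenchymal 1.05, nephron and podocyte -0.07, trophoblast and amnion 0.35. On chip 1, Neg against Low: basement membrane 0.57, blood 1.8, cell cycle -0.31, endothelial 2.06, epithelial -0.6, HOX 0.36, liver and yolk sac 0.33, mesenchymal 0.66, primitive streak -1.22. There Low against Diff reversed for endothelial genes (-0.4), and Neg against hESC for the gene HBG2 (2.09).

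On chip 2, Neg against hESC: basement membrane -0.28, blood -1.55, cell cycle 0.02, endothelial -0.48, HOX -1.34, lateral plate -0.82, mesenchymal -1.09, nephron and podocyte -0.93, neural crest -0.73, paraxial mesoderm -0.67, trophoblast and amnion -0.64, WNT targets -0.86. On chip 2, Diff against hESC: blood -2.02, neural crest -0.39, primitive streak -1.15, WNT targets 0.4. In Low against hESC there, neural crest was -0.63 and WNT targets 0.11, in Low against Diff blood was 0.99, and in Neg against Diff cell cycle was 0.08 and epithelial 0.38. A result counts as reversed when its test turned direction, so its median can keep its sign.

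With each array left out in turn, further reversals came only from arrays labelled Neg. Neg against Diff ranged from -0.62 to 0.3 for basement membrane, -0.3 to 0.04 for cell cycle, -2.1 to 0.94 for HOX, -1.51 to 0.53 for lateral plate, -1.09 to 0.53 for liver and yolk sac, -1.64 to 0.53 for mesenchymal, -1.24 to 0.37 for trophoblast and amnion and -1.19 to 0.25 for WNT target genes. Neg against Low ranged from -0.9 to 0.16 for basement membrane and -1.42 to 0.38 for liver and yolk sac.

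No list result reversed in the settings that follow. Of 156, the same call stood in 152 with a chip block (4 lost), 147 with neqc and with quantile normalization (3 lost and 6 gained in each), 143 without a filter (8 lost, 5 gained) and 150 with only both compared groups (1 lost, 5 gained). With an estimated correlation 63 calls were lost. Of 584 gene results, none of them called over 12 arrays, 246 became called with the same sign on chip 1 and HBG2 with the other, 259 became called without the arrays labelled hESC 3 and Neg 2, 148 without Neg 2 and 46 with only both groups. With 1 Diff array dropped from chip 1, 230 (Diff 1) and 278 (Diff 2) became called with the same sign. In all other settings none was called, and another probe of the gene left 48 of 48 uncalled.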

Other observations

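Some genes stood highest on the unsorted differentiated arrays of chip 1, in a set chosen after its values were seen. HBZ, an embryonic globin gene, read 9.26 and 9.29 on the log2 scale on the arrays labelled Diff 1 and Diff 2, and at most 5.69 on the other 4 arrays of the chip. HBE1 read 10.71 and 10.50 there against at most 7.69, and TBXT, the primitive streak gene that encodes brachyury, 6.95 and 6.67 against at most 5.08. In all, 22 genes stood over 1 log2 above the other chip 1 arrays on both Diff arrays, including WNT3A and HES5, which carry WNT and Notch signals. On chip 2, 20 of the 22 were highest on the array labelled hESC 3, HBZ at 6.84 and TBXT at 7.10 among them. Lists with no call for Diff against hESC on chip 1 included definitive endoderm (median 0.57), hypoxia and glycolysis (0.00), ribosomal (-0.11), handling stress (-0.25) and epithelial genes (-0.39).

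All tests in the paragraphs that follow were written after the result they address was seen, except the test of the authors' normalization on the array labelled Diff 1.

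Pluripotency and lateral plate genes differed between arrays of the same label on both chips, and 3 explanations were tested. Labels of the chip 2 arrays moved by 1 position could explain this: the shift ranked 1 of 180 distinct assignments by mean correlation with the chip 1 groups (0.975, the next 0.973, the deposited labels rank 82 at 0.934), but it was found from the same correlations and the arrays' true origin cannot be told from these values. A processing difference between the chips is unlikely to be the whole cause, since it would move each label alike, and across probes, which are not independent replicates, the chip 2 minus chip 1 difference of the hESC label correlated at -0.676 with that of the Neg label, and the Low label's at -0.437 with it, though the other 4 pairs of labels correlated at 0.056 to 0.247, so a smaller shared part stays open. Cultures that differed between passages stay open, as the test could not decide. It predicted the array labelled Neg 2 between the chip 1 hESC and Neg arrays, over 1 log2 from the hESC mean on both lists. That was not met: its pluripotency genes lay a median of -0.13 from the chip 1 hESC mean and its lateral plate genes 0.23. The arrays labelled hESC 2 and hESC 1 differed by -0.06 and 0.54. The rule against this cause also required a pluripotency fall over 1 log2, so an array like hESC could not reject it. The array labelled hESC 3 lay -0.70 and 2.85 from the chip 1 hESC mean. No array was moved to another label for any value given here.

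The array labelled Diff 1 set the second principal component and had the lowest mean unnormalized intensity of the 11 arrays with such values. Loss of part of its RNA or amplified product could explain this, since 47.5% of 955 genes with several probes had probes over 1 log2 apart on it once each probe's mean over the 12 arrays was subtracted, against 22.8% on the next array. The authors' background correction or normalization is unlikely to be the whole cause. With quantile normalization and no background correction, 43 genes still lay over 1 log2 below every other array on it, against 3 on the next. With the authors' normalization, over 12 arrays, the counts were 270 and 50. The size of the pattern thus depended on the processing. A biological difference of that culture was not tested.

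Pluripotency genes were lower on the array labelled Neg 1 than on the array labelled Low 1, as the design's GCTM-2 sort might produce. A loss of RNA like that of the array labelled Diff 1 is unlikely to be the whole cause, since 11 pluripotency genes within 0.5 log2 between both Diff arrays of chip 1 still had a median of -1.34, with 10 of 11 lower. Whether such a loss adds to it stays open. The Neg 1 minus Low 1 difference correlated at 0.431 with the Diff 1 minus Diff 2 difference. That correlation ran over all 11272 genes, which are not independent replicates. Of genes with several probes, 20.7% had probes over 1 log2 apart on the array labelled Neg 1 against 4.3% on Low 1. The same share was 22.8% on hESC 1 and 15.6% on hESC 2, so it does not single out Neg 1. Only 1 gene lay over 1 log2 below every other array on Neg 1, against 270 on Diff 1. A constant share of undifferentiated cells on the array labelled Low 1 could not be told apart from other causes: the share per gene ran from 7.65% to 20.7% between quartiles over 18 genes, a ratio of 2.71. A true difference between the sorted populations stays open and rests on 1 array of each.

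Splitting the 6 arrays of each comparison into other groups of 3 gave at least as many called probes as the deposited labels in 10 of 10 splits in every comparison, the deposited one included. Those labels gave 0, so this was bound to happen and tests nothing, and 10 splits are too few for a share under 0.05. The most for another split was 0 for Diff against hESC, Low against hESC and Low against Diff, 18 for Neg against Diff and 74 for Neg against Low. The 74 came from the arrays labelled Low 1, Neg 2 and Neg 3 against those labelled Neg 1, Low 2 and Low 3. That split exchanges the Low and Neg labels of chip 2, and no other split of that comparison gave a call. For Neg against hESC the most was 3865, for the arrays labelled hESC 1, hESC 2 and Neg 2 against those labelled hESC 3, Neg 1 and Neg 3, which restates the unlike values of the arrays labelled hESC 3 and Neg 2.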
